A study of Homo sapiens with 4 samples.

How the data were processed

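Total RNA was taken from human umbilical vein endothelial cells, passages 6 to 8, that were grown to 70% confluency and infected for 48 h with adenovirus carrying KLF4 (Ad-KLF4, 2 libraries) or the empty vector (Ad-Null, 2 libraries), per the labels' protocols. Per the submitters' processing notes, bcl2fastq, TopHat2 2.0.14, Cufflinks 2.2.1 and the human genome build hg19 were used; the role of each, the annotation, the strand setting and how libraries were scaled to each other are not given in the sources used here. The deposited table holds FPKM values per locus made by the authors, with Cufflinks locus identifiers and gene symbols per the file headers. The table does not name its unit, and FPKM was inferred from the tool named in the notes and from the values. If strand was not used, reads of a gene and of an overlapping or antisense neighbour cannot be told apart.

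The table has 26879 rows for 26006 loci. Rows that give several symbols to 1 locus (616 loci) repeat identical values and were counted once, under all their symbols. Another 545 symbols stand at several loci, and the locus with the highest mean was used for them. No pair of libraries held an identical value above 0 among the tested loci, so none was treated as a repeat of another. The series design calls the cultures biological duplicates; whether they came from separate donors is not given in the sources used here. FPKM keeps no read totals, and the number of reads behind a value is therefore unknown. At loci with a mean under 0.15 FPKM, 78.3% to 81.0% of the values compared with Ad-Null replicate 1 stood in a ratio of whole numbers up to 5, within 2%, against 21.3% to 22.2% for a random step. This spacing gave relative depths of 1, 1.44, 1.00 and 1.29 for Ad-Null 1, Ad-Null 2, Ad-KLF4 1 and Ad-KLF4 2. It does not give counting errors, so errors here are the spread between libraries, and no detection limit is stated. The locus of MIR6723 alone held 5.58% to 8.08% of the summed FPKM. A value of 0 can be a failed or shared estimate: of 136 core genes looked up, 2 were at 0 in all libraries. Such genes are described as listed at 0, with the value of each library and no fold.

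Values were tested as log2(FPKM + 1), which understates the change of low genes, at the 11856 loci with a mean of at least 1 FPKM over all 4 libraries (165 of them small RNA loci). The test was limma 3.58.1 in R 4.3.3 (linear model per locus, moderated variance with a mean trend), two-sided, with Benjamini-Hochberg adjustment over all loci and a threshold of 0.05. Folds are ratios of mean FPKM; where the lower group was near 0, the values of each library are given. Adjusted p-values in the text come from limma, including its gene list tests. The 26 gene lists were fixed before the data were examined, as were the rule for named genes and the main design. A locus under 1 FPKM in 1 group passes the filter only if the other group is high, so lists with such members are also given with no filter. The lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists with at least 2 tested members; the mitochondrial list had none and was not analysed here. At that setting 14 lists passed, the fibroblast list among them. That list is not counted as a result, since its 2 tested members passed the filter only through their Ad-KLF4 values. With a correlation estimated per list 0 passed. The estimated setting judges each list on the few residual degrees of freedom of 4 libraries. A pass after adjustment over 25 lists was nearly out of reach there, so its p-values decide nothing about a list. The companion test fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes, passed for 18 lists, and its mixed form, for change in either direction, for 24.

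Named genes are KLF4, the 15 largest increases and 15 largest decreases among called loci with non-overlapping groups (passing over loci named only by locus numbers or as small RNAs), up to 4 called members of each list by size of change (or, if none was called, up to 2 with the highest level), from which examples were taken, and 14 genes chosen in advance for their place in sterol, nitric oxide, adhesion and endothelial biology. XIST and Y-linked genes were left out of naming. Some genes that the rule named are not reported here; counts and tests include them. The 2 lists of the flow and nitric oxide kind share genes, as do others. Markers of other cells came from the smooth muscle, fibroblast, leukocyte and erythroid, and epithelial lists.

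The limma step was tested on simulated data for the same comparison and 11856 loci. With 4000 genes changed by 0.5, 1 or 2 on the log2 scale, 64.9%, 98.6% and 99.4% were recovered, and 2.6% to 2.8% of the calls were false. With 200 changed genes the shares recovered were 0.1%, 88.1% and 98.9%, and 90%, 7.6% and 9.3% of the calls were false. In 20 simulated sets a list of 20 genes raised by log2 1 was called 20 times, and 2 of 40 unchanged lists were called. List calls there used an unadjusted p under 0.05. Noise was drawn independently for each gene and library in both simulations, with the variance the model estimated, the same in both groups. The simulations therefore do not show how many calls are false where genes vary together, as with the GC and length trends between the libraries. Nor do they show it where the groups differ in spread. In the data the Ad-KLF4 pair was the noisier (SD of log2 differences 0.520 against 0.400 for the Ad-Null pair). The alternatives tried were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, quantile normalization, scaling to a common median, limma without a mean trend, a replicate block, each library left out, an added limit of log2 1 on the change, and an estimated correlation for lists. Leaving out small RNA loci and correcting each library for transcript GC content (11199 loci, or 94.5%, with a value) were added after seeing the data. GC content and length came from a later human annotation than that of the table, matched by symbol, and neighbouring genes from RefSeq on GRCh38.p14, so no coordinates are given. With 2 libraries per group no exact permutation test can reach 0.05, and outlier rules and other splits of the samples were not applied. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.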

Results

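RNA was sequenced from human umbilical vein endothelial cells (HUVEC), primary cells that line the vein of the umbilical cord, 48 h after infection with an adenovirus. In 2 cultures the virus carried KLF4, a zinc finger transcription factor of the vascular endothelium (Ad-KLF4), and in 2 control cultures it was the empty vector (Ad-Null). The series design describes the cultures as biological duplicates. Expression was given for 26006 loci in a unit inferred to be FPKM, fragments per kilobase of transcript relative to library size; how the libraries were scaled to each other is not given in the sources used here. Summed FPKM was 551737 and 557057 in the Ad-Null libraries and 532008 and 505868 in the Ad-KLF4 libraries. The number of reads per library is unknown, but the spacing of the lowest values placed the relative depth at 1 and 1.44 for Ad-Null replicates 1 and 2, and at 1.00 and 1.29 for Ad-KLF4 replicates 1 and 2. Across the 11856 loci with a mean of at least 1 FPKM, log2 values of the Ad-Null pair correlated at Pearson's r = 0.978 and those of the Ad-KLF4 pair at 0.962, both across genes, which are not independent replicates. The difference between the 2 Ad-KLF4 libraries followed transcript GC content (Spearman's rho = 0.63 across genes), more than that between the Ad-Null libraries (0.27). It also followed transcript length, longer transcripts being lower in replicate 1 relative to replicate 2 (rho = -0.40, against 0.05 for the Ad-Null pair). Against Ad-KLF4 replicate 2 the differences of the 2 Ad-Null libraries had a rho of -0.16 and -0.18 with length, and against replicate 1 of 0.04 and 0.02.

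The single comparison of the design asks which genes of these cells change when KLF4 is raised. KLF4 itself was read first, since it checks the labels. It stood at 1.04 and 1.63 FPKM in the Ad-Null libraries and at 403 and 220 FPKM in the Ad-KLF4 libraries, a 233-fold higher mean (1.34 ± 0.417 against 312 ± 129 FPKM, SD, n = 2 each). On the log2(FPKM + 1) scale the change was 7.01 ± 0.30 (SE; limma, adjusted p = 1.91e-04). Whether the insert is human KLF4 and which untranslated regions it has is not given in the sources used here, so the share of its reads that these values hold is unknown, and reads of the cells' own gene are not separated from it. The KLF4 value of Ad-KLF4 replicate 1 was 1.83 times that of replicate 2.

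KLF4 overexpression changed 5072 of the 11856 loci (limma, Benjamini-Hochberg adjusted p under 0.05), of which 1914 rose and 3158 fell. A change of at least 1 on the log2 scale was reached by 1638 of them, 848 upward and 790 downward. The largest increase was that of PI16, a secreted peptidase inhibitor, from 0.224 and 0.233 FPKM to 1477 and 1017 FPKM (log2 change 9.96 ± 0.19 SE, adjusted p = 5.65e-05). TRH, the thyrotropin-releasing hormone precursor, was listed at 0 in both Ad-Null libraries and at 607 and 388 FPKM in the Ad-KLF4 libraries. CD52, a small glycoprotein best known from lymphocytes, was listed at 0 in both Ad-Null libraries and reached 497 and 343 FPKM, and the calcium-binding protein S100P went from 0 in both to 384 and 237 FPKM. The water channel AQP3 rose from 0.822 and 0.613 to 533 and 399 FPKM, and the water channel AQP1 from 1.98 ± 0.421 to 199 ± 9.03 FPKM (SD, n = 2 each). Other large increases were in LYPD2, in the locus shared by IGF2, INS and their read-through transcript, in the retinoic acid carrier CRABP2, in the kallikrein-related peptidases KLK13 and KLK10, in the potassium channel KCNN4 and in the cornified envelope gene CNFN. Values of the shared IGF2 locus, 1.45 and 1.53 against 389 and 316 FPKM, cannot be divided between its genes.

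The largest decrease was that of the fatty acid carrier FABP4, from 65.0 ± 1.41 to 3.60 ± 0.883 FPKM (SD, n = 2 each), 18.0-fold lower (log2 change -3.85 ± 0.16 SE, adjusted p = 1.82e-04). FABP5 was 8.51-fold lower, from 600.2 ± 6.58 to 70.5 ± 5.71 FPKM. KLF2, a related transcription factor of the endothelium, fell from 43.9 and 43.6 FPKM to 5.75 and 3.83 FPKM, 9.13-fold lower (adjusted p = 4.47e-04). ANGPT2, an antagonist of the TEK receptor, was 10.4-fold lower, the chemokine receptor CXCR4 8.60-fold lower, the metalloproteinase MMP10 13.0-fold lower and the protease inhibitor TFPI2 5.75-fold lower. The metallothionein MT2A dropped from 2397 ± 105 to 328 ± 56.3 FPKM. Lower levels were also found for the locus shared by CCL14 and CCL15, for C10orf10 and LY6K, for the amino acid synthesis enzymes ASNS and PSAT1 and for the cell cycle genes PLK1 and MYBL2, each with an adjusted p of 0.00145 or less. Among the largest decreases, 15 loci named only as small RNAs or by locus numbers were passed over.

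**Figure D1:**
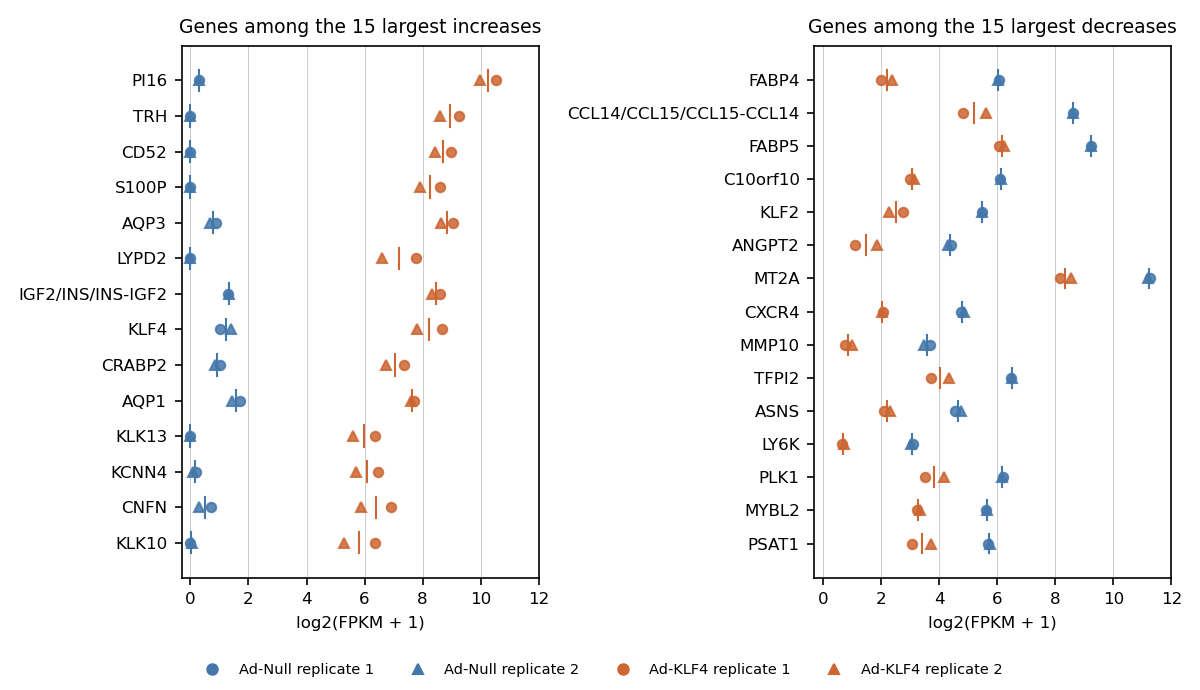
Expression of 14 of the 15 genes with the largest increases (left) and of those with the 15 largest decreases (right), as log2(FPKM + 1) on the horizontal axis; each point is 1 library, blue for Ad-Null and orange for Ad-KLF4, and the short bars are group means. Genes were picked among loci whose groups do not overlap, and PI16 lies near 0.2 FPKM in Ad-Null against 1017 and 1477 FPKM in Ad-KLF4.

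Both Ad-KLF4 libraries lay on the same side of both Ad-Null libraries at 75.5% of the tested loci, where exchangeable libraries would give 33.3% on average. Loci are not independent, and differences that run through a whole library can also raise this share, so it is not a test of KLF4. The median log2 change of all tested loci was -0.12; scaling every library to a common median, which shifts all loci of a library alike, gave 2415 increases and 2359 decreases, and quantile normalization gave 2150 and 2759. Correction for GC content, added after seeing the data, gave 1988 and 4424. The count fell to 1702 without Ad-Null replicate 1 and to 1716 without Ad-Null replicate 2, fits in which the spread comes from the Ad-KLF4 pair alone.

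Genes associated with laminar blood flow and with KLF2 or KLF4 in the endothelium rose together. Of the 19 measured members of this list 15 rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone and a median log2 change of 3.03 (camera, adjusted p = 2.70e-09). With an inter-gene correlation estimated from the data, the list gave adjusted p = 0.327. Of those that rose, 5 were under 1 FPKM in Ad-Null and passed the filter only through their Ad-KLF4 values, and with no filter 15 rose and 2 fell of 20 (camera, adjusted p = 6.44e-08). Besides PI16 and AQP1, the matricellular protein NOV (CCN3) went from 0.440 and 0.640 to 86.5 and 78.2 FPKM and the monooxygenase CYP1B1 from 0.320 and 0.502 to 68.1 and 66.7 FPKM. NOS3, the endothelial nitric oxide synthase, was 9.43-fold higher (115 ± 1.49 against 1086 ± 310 FPKM, SD, n = 2 each; adjusted p = 4.73e-04). The member that fell was KLF2, so genes of this list were high in the cultures with the lowest KLF2.

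Genes of nitric oxide and calcium signalling shifted upward as a list. Of 19 measured members 10 rose and 3 fell, with the same counts adjusted over the list alone (camera, adjusted p = 8.57e-04; adjusted p = 0.327 with an estimated correlation). The calcium pump ATP2A3 went from 0.479 ± 0.0819 to 65.2 ± 17.3 FPKM. ITPR3, an inositol trisphosphate receptor that releases stored calcium, was 3.39-fold higher (28.9 ± 1.21 against 97.9 ± 5.84 FPKM; adjusted p = 4.42e-04). GCH1, which makes the cofactor of nitric oxide synthase, was 3.97-fold higher. NOS3 and ITPR3 are members of this list and of the flow list. Of the nitric oxide and calcium genes 1 that rose passed the filter only through its Ad-KLF4 values. With no filter 9 of these genes rose and 1 fell of 20 (camera, adjusted p = 9.23e-04). With either Ad-Null library left out 6 rose and 0 fell, and only 1 fell with no filter, under both other scalings and without a mean trend.

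Cholesterol efflux and liver X receptor genes shifted upward as a list. Of 10 measured members 7 rose and 1 fell (8 and 2 adjusted over the list alone), with a median log2 change of 0.73 (camera, adjusted p = 0.00799; adjusted p = 0.327 with an estimated correlation). Leaving out Ad-Null replicate 1 left 2 higher and 0 lower, leaving out Ad-Null replicate 2 left 3 and 0, and leaving out Ad-KLF4 replicate 1 gave 8 and 2. GC correction gave 7 and 2, at a filter of 5 FPKM 4 rose and 1 fell of 7, and with no filter 6 rose and 1 fell of 12. The sterol exporter ABCG1 was 3.47-fold higher (4.38 ± 0.224 against 15.2 ± 0.658 FPKM, adjusted p = 7.06e-04), and the lipid carrier APOE rose from 0.324 and 0.673 to 102 and 49.4 FPKM. NR1H3, which encodes the receptor LXR alpha, was 2.44-fold higher (adjusted p = 0.0213), a call lost without Ad-Null replicate 1 (0.0693) or replicate 2 (0.140), with adjusted p up to 0.140 over its alternatives. CH25H, the enzyme that makes 25-hydroxycholesterol, lay below the filter at 0.0897 and 0 FPKM in Ad-Null and 0.179 and 0.139 FPKM in Ad-KLF4. Without the filter on low values its adjusted p was 0.143. The exporter ABCA1 also lay below the filter, at 0.256 and 0.298 against 1.44 and 1.41 FPKM, with an adjusted p of 0.00397 when low loci were kept. Sterol synthesis and LDL uptake genes did not pass as a list against other genes (1 rose and 7 fell of 18, also adjusted over the list alone; camera, adjusted p = 0.443). Of them 3 fell under either other scaling, 3 with no filter and 4 without a mean trend. The counts were 0 and 1 without Ad-Null replicate 1, 0 and 2 without Ad-Null replicate 2, 2 and 5 without Ad-KLF4 replicate 1 and 2 and 9 without Ad-KLF4 replicate 2.

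**Figure D2:**
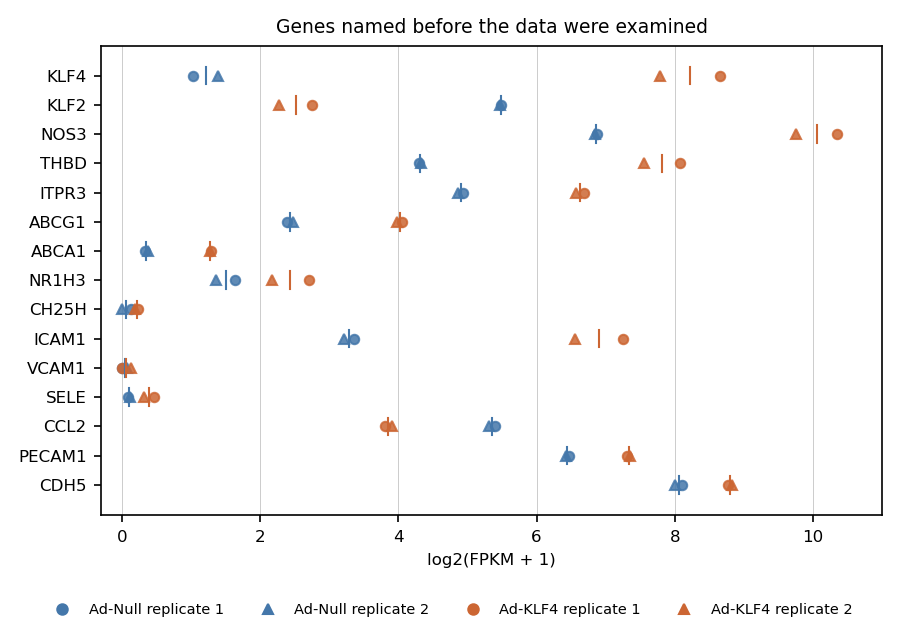
Expression of KLF4 and of 14 genes fixed in advance, as log2(FPKM + 1) on the horizontal axis; each point is 1 library, blue for Ad-Null and orange for Ad-KLF4, and the short bars are group means. NOS3, THBD and ICAM1 are higher and KLF2 and CCL2 lower in both Ad-KLF4 libraries, while VCAM1, SELE and CH25H stay under 0.4 FPKM in every library.

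Genes of leukocyte adhesion and inflammation moved in both directions. Of 12 measured members 6 rose and 2 fell, with the same counts adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0651), while fry put it higher (adjusted p = 0.00940). It passed in 3 of 14 alternatives, namely with a filter at 5 FPKM (0.0466), without Ad-Null replicate 1 (0.0450) and without Ad-Null replicate 2 (0.0400), within a range of 0.0400 to 0.448. Without Ad-Null replicate 1 the counts were 3 and 2, and with no filter 8 rose and 5 fell of 25. The adhesion molecule ICAM1 was 13.9-fold higher (8.80 ± 0.691 against 122 ± 40.5 FPKM, adjusted p = 5.16e-04), P-selectin (SELP) 7.66-fold higher and the NF-kB inhibitor NFKBIA 4.58-fold higher. The chemokines CXCL8 and CCL2 were 3.88-fold and 2.96-fold lower. VCAM1 was near 0 in both groups, with 0.0537 FPKM as the higher Ad-Null value and 0.0898 FPKM as the higher Ad-KLF4 value. E-selectin (SELE) was at 0.0575 and 0.0796 FPKM in Ad-Null and 0.373 and 0.244 FPKM in Ad-KLF4. Without the filter on low values SELE passed with an adjusted p of 0.0364 and VCAM1 did not (0.804). Of the 26 genes of the list, the other 14, VCAM1 and SELE included, lay below the filter.

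Coagulation and fibrinolysis genes moved in both directions. Thrombomodulin (THBD), which turns thrombin towards protein C, was 12.1-fold higher (18.8 ± 0.226 against 228 ± 58.1 FPKM; adjusted p = 3.25e-04), and urokinase (PLAU) was 2.75-fold higher. TFPI2 fell, and the protease-activated receptor F2RL1 was 5.29-fold lower. In all 8 of 15 members rose and 3 fell (8 and 4 adjusted over the list alone; camera, adjusted p = 0.0493; adjusted p = 0.327 with an estimated correlation). Without Ad-KLF4 replicate 2 the counts were 8 and 6, and after GC correction 8 and 5. The list no longer passed without Ad-Null replicate 2 (0.0603), without Ad-KLF4 replicate 2 (0.190), at a pseudocount of 0.1 (0.0588), with no filter (0.0770), after scaling to a common median (0.117), with a replicate block (0.0557) or without small RNA loci (0.0503), and it passed in 6 of 14 alternatives, with a range of 0.0346 to 0.327.

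Nearly all cell cycle genes measured were lower. All 20 DNA replication and G1/S genes fell, with a median log2 change of -1.77 (camera, adjusted p = 2.70e-09; adjusted p = 0.344 with an estimated correlation). Among them the helicase subunit MCM2 was 4.68-fold lower (43.8 ± 4.10 against 9.36 ± 2.31 FPKM) and the ribonucleotide reductase subunit RRM2 4.35-fold lower. Of 20 G2/M and mitosis genes 19 fell, with a median of -1.86 (camera, adjusted p = 3.71e-07; adjusted p = 0.345 with an estimated correlation). MKI67, a marker of proliferating cells, was 5.07-fold lower and the survivin gene BIRC5 5.15-fold lower. Adjusted over each list alone the counts were the same. The member that did not pass was AURKA, singled out after its values were seen. It measured 31.7 ± 0.533 FPKM in Ad-Null and 73.6 ± 87.2 FPKM in Ad-KLF4 (SD, n = 2 each), where replicate 1 alone lay above the Ad-Null libraries, at 135 FPKM. Leaving out that library, 20 of the 20 mitosis genes fell, and leaving out Ad-KLF4 replicate 2, 19 fell and 1 rose.

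Endothelial identity genes shifted upward as a list. Of 22 measured members 10 rose and 4 fell, also adjusted over the list alone (camera, adjusted p = 0.0210; adjusted p = 0.327 with an estimated correlation). Leaving out either Ad-Null library gave 7 and 0, and leaving out Ad-KLF4 replicate 2 gave 12 and 7. Scaling to a common median gave 10 and 2, and GC correction 11 and 7. The angiopoietin receptor TEK was 6.65-fold higher (29.4 ± 0.151 against 196 ± 4.23 FPKM), CD34 was 4.33-fold higher and the VEGF receptor FLT1 rose by 1.53 ± 0.10 (SE) on the log2(FPKM + 1) scale. The junction genes PECAM1 and CDH5 were 1.86-fold and 1.67-fold higher, with adjusted p of 0.00169 and 0.00294. The call of CDH5 was lost without Ad-Null replicate 1 (0.0515) or replicate 2 (0.0720, the highest of its alternatives). The tight junction gene CLDN5 was 2.39-fold lower (adjusted p = 0.0119; 0.0637 without Ad-Null replicate 1, its highest, and 0.0586 without replicate 2). The list itself was no longer called without Ad-KLF4 replicate 1 (0.0854) or replicate 2 (0.0558) or after GC correction (0.0503, with its median log2 change at 0.08 in place of 0.31), and it passed in 10 of 14 alternatives, in a range of 0.0149 to 0.327.

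Angiogenesis and tip cell genes were mostly lower. Of 18 measured members 12 fell and 2 rose (12 and 4 adjusted over the list alone; camera, adjusted p = 0.0448; adjusted p = 0.327 with an estimated correlation). ANGPT2, CXCR4 and MMP10 led the decreases, whereas the growth factor VEGFA was 4.08-fold higher. Increases numbered 4 with no filter and after scaling to a common median. The list passed in 8 of 14 alternatives, in a range of 0.0139 to 0.327. It was lost without either Ad-KLF4 library (0.0645 without replicate 1), at a pseudocount of 0.1 (0.0595), with no filter (0.0980) and after GC correction (0.0738). Arterial and Notch genes split evenly, with 6 higher and 6 lower of 18 (7 and 7 adjusted over the list alone, 3 and 3 without either Ad-Null library in turn; camera, adjusted p = 0.481): the Notch modifier LFNG was 9.98-fold higher and DLL1 5.67-fold higher, while CXCR4 was lower. Among 9 venous and lymphatic genes 4 rose and 1 fell, also adjusted over the list alone; 0 fell without either Ad-Null library in turn 3 fell after GC correction and 4 fell without Ad-KLF4 replicate 2. The median log2 change of this list was -0.07 while its mean was 1.08 (camera, adjusted p = 0.101; 0.292 with no filter; fry, higher, adjusted p = 0.00940), since ACKR1 (0 and 0.0703 against 32.8 and 25.8 FPKM) and APLNR (0.0606 and 0 against 26.8 and 20.8 FPKM) rose far more than the others. Both passed the filter only through their Ad-KLF4 values. Among the arterial and Notch genes 1 passed it only through its Ad-KLF4 values and 1 only through its Ad-Null values. With no filter 7 arterial and Notch genes rose and 6 fell of 20 (camera, adjusted p = 0.448).

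**Figure D3:**
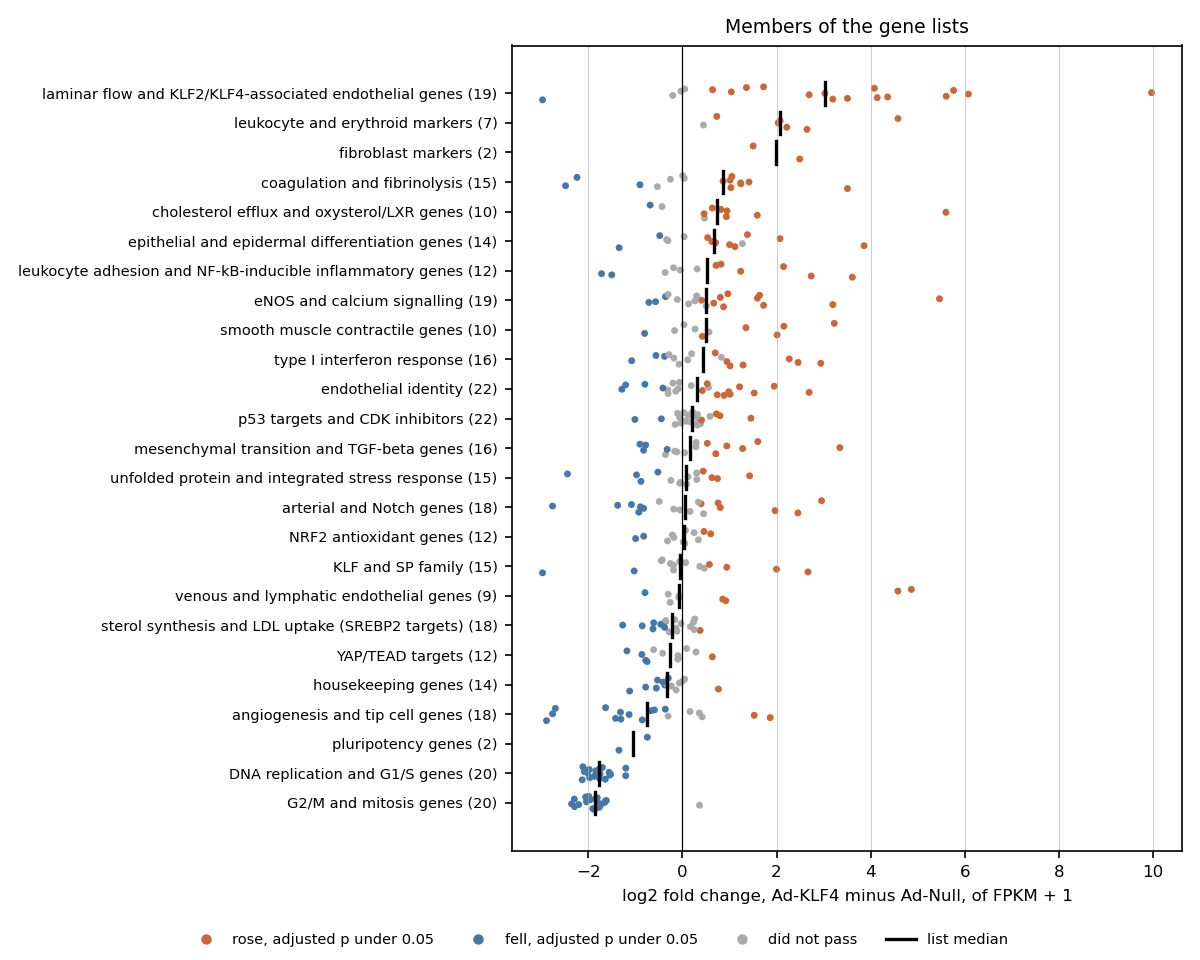
Log2 fold changes (Ad-KLF4 minus Ad-Null, of FPKM + 1) of the members of 25 gene lists, 1 row per list with the number measured in brackets; orange points rose, blue points fell, grey points did not pass an adjusted p of 0.05, and black bars are list medians. The flow list has the highest median (3.03), and the replication and mitosis lists the lowest (-1.77 and -1.86).

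Several markers of other cell types were higher in the Ad-KLF4 cultures. Of 7 measured leukocyte and erythroid markers 6 rose, also adjusted over the list alone (camera, adjusted p = 2.86e-05; adjusted p = 0.327 with an estimated correlation). Of these 7, 6 had an Ad-Null mean under 1 FPKM and passed the filter only through their Ad-KLF4 values, and with no filter 7 rose and 0 fell of 9 (camera, adjusted p = 5.27e-05). Members near 0 in Ad-Null had no room to fall, with or without the filter. The haemoglobin gene HBA1, whose reads can be shared with its copy HBA2, was listed at 0 in both Ad-Null libraries and reached 31.5 and 16.6 FPKM. The monocyte co-receptor CD14 went from 0.159 and 0.166 to 9.22 and 4.18 FPKM, and the lysosomal protein CD68 was 4.78-fold higher. The pan-leukocyte gene PTPRC, named after its values were seen, stayed at 0.0516 FPKM or less in every library. Smooth muscle contractile genes gave 5 increases and 1 decrease of 10 (7 and 1 adjusted over the list alone; camera, adjusted p = 0.00976; adjusted p = 0.327 with an estimated correlation), led by CSPG4 (0.0261 and 0.0543 against 10.4 and 7.30 FPKM), with TAGLN 4.24-fold and TPM2 2.59-fold higher. This list did not pass with a filter at a mean of 5 FPKM (0.0628; range 0.00495 to 0.327), where 2 rose and 1 fell of 8. CSPG4 and DES (0 and 0 against 4.53 and 2.59 FPKM) passed the main filter only through their Ad-KLF4 values; with no filter 5 rose and 1 fell of 14 (camera, adjusted p = 0.00875). Its counts were 4 and 0 with either Ad-Null library left out and 6 and 2 without Ad-KLF4 replicate 2.

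Of 14 measured epithelial genes 8 rose and 2 fell (9 and 2 adjusted over the list alone; camera, adjusted p = 0.00976; adjusted p = 0.327 with an estimated correlation). With either Ad-Null library left out 4 rose and 1 fell, and with no filter 13 rose and 2 fell of 32 (camera, adjusted p = 0.00184). Of the 14, 4 passed the filter only through their Ad-KLF4 values, and 3 of these rose, DSP, PPL and KRT13. The desmosome gene DSP went from 0.0443 and 0.0189 to 3.36 and 3.33 FPKM, and the cell envelope gene PPL from 0.699 and 0.448 to 2.81 and 3.39 FPKM, whereas KRT7 was 2.57-fold lower. At a filter of 5 FPKM the list had adjusted p = 0.0915 (range 0.00184 to 0.327), with 5 higher and 2 lower of 8. Only 2 of 12 fibroblast markers passed the filter, PDGFRB and THY1, PDGFRB at 0 and 0.0265 against 5.52 and 3.98 FPKM and THY1 at 0.144 and 0.0999 against 2.06 and 2.30 FPKM. Both passed it only through their Ad-KLF4 values, so the list was read with no filter, where 4 rose and 2 fell of 11 and it did not pass (camera, adjusted p = 0.171).

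Type I interferon genes gave 7 increases and 3 decreases of 16 (8 and 3 adjusted over the list alone; camera, adjusted p = 0.0314; adjusted p = 0.327 with an estimated correlation). Without Ad-Null replicate 1 the counts were 4 and 1, and without replicate 2 they were 5 and 0. Of those that rose, 2 passed the filter only through their Ad-KLF4 values, and with no filter 7 rose and 2 fell of 22. MX1 went from 0.744 ± 0.225 to 12.4 ± 2.21 FPKM (SD, n = 2 each), OAS1 was 6.58-fold higher and IFI27 4.99-fold higher. The list did not pass without Ad-KLF4 replicate 1 (0.0687) or replicate 2 (0.0641), with no filter (0.0770) or after scaling to a common median (0.0621), in a range of 0.0103 to 0.327. Of 22 targets of p53 and cyclin-dependent kinase inhibitors 4 rose and 2 fell (3 and 2 adjusted over the list alone; camera, adjusted p = 0.0421; adjusted p = 0.345 with an estimated correlation), with the death receptor FAS 3.40-fold higher. It did not pass fry in 1 direction (adjusted p = 0.0869). Those counts were 1 and 0 without Ad-Null replicate 1, 1 and 1 without Ad-Null replicate 2, 7 and 3 without Ad-KLF4 replicate 1 and 8 and 2 without Ad-KLF4 replicate 2, with 6 and 1 after scaling to a common median and 6 and 4 after GC correction. That list did not pass with no filter (0.0682), after GC correction (0.0704), without Ad-Null replicate 2 (0.0701) or without Ad-KLF4 replicate 1 (0.141), in a range of 0.00884 to 0.345.

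The remaining lists did not pass camera, which compares a list with other genes. The companion test fry, which does not, passed for the housekeeping list (lower, adjusted p = 0.00445) and the mesenchymal list (higher, adjusted p = 0.0157). By fry the pluripotency list, with 2 tested members, passed as well (lower, adjusted p = 0.0157). In the KLF and SP family 4 rose and 2 fell of 15, also adjusted over the list alone (camera, adjusted p = 0.300), with 4 and 5 when Ad-KLF4 replicate 2 was left out and also after GC correction, and 4 and 3 of 17 with no filter. KLF3 was 6.95-fold higher (9.14 ± 0.0727 against 63.5 ± 3.96 FPKM), KLF8 went from 0.183 and 0.196 to 3.55 and 3.97 FPKM, and KLF6 was 2.09-fold lower. Among 16 mesenchymal genes 6 rose and 4 fell (7 and 4 adjusted over the list alone; camera, adjusted p = 0.101), with S100A4 11.4-fold, the inhibitory SMAD7 3.90-fold and MMP2 1.93-fold higher. Of 12 pluripotency genes only MYC and DNMT3B passed the filter (camera, adjusted p = 0.0955); both fell, also adjusted over the list alone, MYC by 2.61-fold. DNMT3B passed it only through its Ad-Null values, and with no filter 0 rose and 2 fell of 9 (camera, adjusted p = 0.714). The unfolded protein list had 4 increases and 4 decreases of 15 (5 and 4 adjusted over the list alone; camera, adjusted p = 0.465), with the chaperone HSP90B1 2.66-fold higher and ASNS 6.65-fold lower. The NRF2 list had 2 of each among 12 (camera, adjusted p = 0.582; 1 of each with no filter, 4 and 1 under either other scaling, 3 and 5 after GC correction) and the YAP/TEAD list 1 increase and 4 decreases of 12 (camera, adjusted p = 0.376), both also adjusted over the list alone, with ARHGEF17 2.53-fold lower. Of 14 housekeeping genes 1 rose and 7 fell (1 and 9 adjusted over the list alone; camera, adjusted p = 0.173), ACTB by 2.17-fold, and 2 of them fell after scaling to a common median, 3 after quantile normalization and 4 with no filter. With either Ad-Null library left out the counts were 4 and 0 in the mesenchymal list, 0 and 1 in the pluripotency, YAP/TEAD and housekeeping lists, 1 and 2 in the unfolded protein list and 0 and 0 in the NRF2 list, and without Ad-KLF4 replicate 2 they were 1 and 7 in the YAP/TEAD list. Mitochondrially encoded genes were not analysed here.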

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

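The alternatives without small RNA loci and with GC correction were chosen after seeing the data; the others were planned. KLF4 stayed called in all 13 alternatives, with log2 changes from 6.58 to 7.73. The count of changed loci stayed within 1.5 times of 5072 under another pseudocount, other filters, other scalings, no mean trend and both added alternatives. It ranged from 1702 to 6741 when 1 library was left out, with 854 to 2469 increases and 816 to 4272 decreases. The low counts came without Ad-Null replicate 1 (1702, of which 854 rose and 848 fell) and without Ad-Null replicate 2 (1716, of which 900 rose and 816 fell). In those fits the lone control is assumed to vary like the Ad-KLF4 pair, which is the noisier one (SD of log2 differences 0.520 against 0.400). Of the main calls 1668 and 1689 were kept there. A limit of log2 1 on the change left 1638 loci, 848 higher and 790 lower, by its construction. The number of gene lists past the threshold dropped from 14 to 9 with no filter on low values, where the cause was not tested. It dropped to 0 with an estimated inter-gene correlation, where list calls have a camera adjusted p of 0.327 to 0.345. That setting judges each list on the few residual degrees of freedom of 4 libraries, so a pass was nearly out of reach. Even the flow list had an unadjusted camera p of 0.0483 there, against 2.16e-10 at the preset correlation. The drop to 0 therefore decides nothing about the lists. Lists with an estimated correlation below the preset 0.01 lost the call too, such as cholesterol efflux (-0.015), nitric oxide and calcium (-0.015) and endothelial identity (-0.024). In these lists the loss therefore does not show that correlated members account for the call.

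Whether the replicate numbers pair the libraries is not known. With only 2 pairs, the deviations of same-numbered libraries correlated at 0.067 across genes, which cannot decide it. A replicate block gave 5147 changed loci in place of 5072, and the coagulation list had an adjusted p of 0.0557 in the block fit. Of 118 named loci with a test, 96 were called in every alternative run on them, and 17 of the other 22 lost the call only without an Ad-Null library. No named locus or called list changed direction. Most named loci were picked for the size of their change among called loci, so the 96 of 118 does not describe all called loci. Loci listed near 0 FPKM in both groups, such as VCAM1 and CH25H, are limited by depth, and an absent change there was not shown.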

Other observations

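The 12 gene families and the tests of counting noise, a KLF4 response, scaling, transcript length, the KLF4 level and the 3 kinds of other cells were chosen after the result was seen, and those of foreign RNA, GC content, selection and neighbouring genes before. Since the families were picked for genes seen to change, only their counts are given, and no test of a family. A member near 0 in 1 group passes the filter only if the other group is high, so the families of this paragraph were counted with no filter. Members near 0 in Ad-Null still had no room to fall, so counts of 0 lower members are partly set by that floor. Over all 17928 loci of that fit 2279 rose and 2940 fell. Of 14 S100 genes, which encode small calcium-binding proteins, 10 rose and 0 fell. S100A2 was 12.3-fold and S100A3 23.9-fold higher. Of 11 kallikrein-related peptidase genes 4 rose and 0 fell. KLK14 went from 0.113 and 0.0785 to 75.5 and 33.9 FPKM. Of 7 aquaporins 5 rose, and of 4 lipocalins 3, with LCN6 at 1.66 and 1.44 against 159 and 103 FPKM. Of 12 LY6/uPAR genes 7 rose and 2 fell, with LYNX1 at 0.866 and 0.567 against 102 and 55.8 FPKM. Of 39 collagen genes 17 rose and 3 fell. Of the 19 that passed the filter 12 rose and 5 fell (12 and 2 after scaling to a common median, 11 and 2 without a mean trend, 8 and 0 when either Ad-Null library was left out), and 5 of them passed it only through their Ad-KLF4 values. COL6A1 was 13.6-fold and COL5A1 3.04-fold higher.

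Of 81 cytosolic ribosomal protein genes 62 fell and 0 rose, with a median log2 change of -0.44. After scaling to a common median 36 fell and 0 rose, after quantile normalization 35 fell and 1 rose, and with no filter 39 of 82 fell and 0 rose. Without Ad-Null replicate 1 only 4 passed and without Ad-Null replicate 2 only 3, while the median log2 change was -0.46 and -0.41. Copies and pseudogenes can share reads with these genes. Over all 11856 tested loci 1914 rose and 3158 fell in the main fit. Both shares of the proteasome subunits below were smaller than that in the main fit. Of 38 translation initiation factors 18 fell and 2 rose, 9 and 2 after scaling to a common median, and 3 and 0 when either Ad-Null library was left out. Of 5 metallothioneins 4 fell and MT1A rose, also under both other scalings, and without Ad-Null replicate 2 no member passed as higher. Of 18 aminoacyl-tRNA synthetases 8 fell and 1 rose (7 and 1 after scaling to a common median, 1 and 1 when either Ad-Null library was left out), of 37 proteasome subunits 6 fell and 3 rose (2 and 3 after scaling to a common median, 15 and 3 after GC correction, 14 and 2 without Ad-KLF4 replicate 1, 12 and 4 without Ad-KLF4 replicate 2, 0 and 0 without Ad-Null replicate 1, 0 and 1 without Ad-Null replicate 2), and of 5 fatty acid binding proteins 2 fell and 1 rose with no filter.

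Loci high in 1 library only were searched among all loci, tested or not, except those holding a MIR, SNOR, RNU or similar small RNA symbol. In Ad-KLF4 replicate 1, 6 of the loci searched reached at least 10 FPKM and 8-fold or more (of FPKM + 1) above every other library, against 2, 0 and 0 in the others. Among them were ARMS2, CYP19A1, PHF11, DNAJC6 and PRNCR1, picked after their values were seen; ARMS2 was at 174 FPKM there and at 0 in Ad-KLF4 replicate 2. If values are whole reads, each of the 6 rested on at least 32 reads in a library that was not the deepest, whose lower 95% Poisson bound of 21.9 lies above the upper bound of 5.57 for 1 read, against counting noise; a few molecules amplified many times stay open. A response to KLF4 stays open: the other Ad-KLF4 library differed from the Ad-Null mean by a median log2 of -0.101 over these loci, but they were picked for being at least 8-fold lower there, which decides nothing. Foreign DNA or RNA in that library may be the source, at 0.11% of its summed FPKM, but it cannot be told apart from other causes without read positions; the AURKA value of 135 FPKM in the same library is open for the same reason.

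Among genes changed by at least log2 1, the response was larger in Ad-KLF4 replicate 1: increased genes lay 0.305 higher there than in replicate 2 (median log2) and decreased genes differed by -0.249. Opposite signs argue against scaling alone. After removing the GC trend between the libraries the median excess in the direction of the change was still 0.204 (SE 0.0068, and 0.278 before). After removing the transcript length trend as well it was again 0.204 (SE 0.0065), against either as the whole cause. Both SEs are the SD over genes divided by the root of their number. They treat genes as independent and do not measure the spread between cultures. Of 1435 genes picked on replicate 2 alone, 75.4% changed more in replicate 1 (exact 95% binomial interval 73.1% to 77.6%, genes not being independent), against selection on a noisier library. The higher KLF4 value of replicate 1, 1.83 times that of replicate 2, is a candidate explanation, but with 1 library at each level it cannot be told apart from other differences between the 2 cultures.

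The rise of markers of other cell types could come from cells other than endothelium. Leukocytes cannot be told apart from other sources: the higher of PTPRC and TYROBP reached 1.23% of CD14 at most, a value set by PTPRC in Ad-KLF4 replicate 2 near the floor, both were listed at 0 in replicate 1, and ITGAM (0 and 0 against 0.580 and 0.341 FPKM) and ITGAX (0.134 and 0.0812 against 3.97 and 3.39 FPKM) rose. Fibroblasts cannot be told apart either: COL1A1 (0.0737 and 0.0511 against 1.67 and 0.641 FPKM) and COL1A2 (0.223 and 0.126 against 0.748 and 0.642 FPKM) were higher in both Ad-KLF4 libraries, LUM was lower and DCN was listed at 0, with the highest of the 4 at 30.3% of PDGFRB. Erythroid cells stay open, since HBB (0.0% of HBA1) and ALAS2 were listed at 0 in every library and a listed 0 can be a failed estimate. Mural cells stay open too (MYH11 at 0.332 and 0.427 against 1.01 and 0.732 FPKM, CNN1 at 0.0589 FPKM or less). So do epithelial cells (EPCAM at 0.348 and 0.193 against 0.417 and 0.161 FPKM, CDH1 at 0.0354 FPKM or less). Of other epithelial genes, KRT5 (0.0502 and 0.0696 against 0.251 and 0.155 FPKM) and KRT14 (0.0736 and 0.0510 against 0.588 and 0.512 FPKM) were higher in both Ad-KLF4 libraries. A hypothesis left open is that the endothelial cells themselves expressed these genes at the KLF4 level reached.

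Strong increases may cluster along the genome. Among 11538 tested loci in genome order, 43 neighbouring pairs had both rises of log2 2 or more, against a mean of 9.45 and a highest value of 24 in 10000 random assignments of the 331 such loci (permutation p = 0.0001, the smallest these can give). Leaving out pairs that overlap or share the first 3 letters of their names gave 24 pairs against a mean of 8.21 and a highest value of 24 (permutation p = 0.0002). The name rule does not remove relatives with unlike names, such as SLURP1 and LYPD2 of the LY6/uPAR family. Runs included SLURP1, LYPD2, LYNX1 and LY6D, and KLK10, KLK13 and KLK14. Only loci past the filter were ordered, so genes that stayed low between them were skipped. Loci near 0 in Ad-Null entered only if they were high in Ad-KLF4, as did all 4 tested kallikreins. The random assignments treat all tested loci alike. Part of the excess can therefore come from the filter, and the p-values do not show that responses cluster. Shared regulation is a candidate explanation, as are read-through transcripts and unresolved strands, which were not tested.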
